A study of Mus musculus with 14 samples.

How the data were processed

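RNA was measured by sequencing in 12 libraries from cultured mouse BFU-E (burst-forming unit-erythroid cells, early progenitors of red blood cells) of C57BL/6 fetal liver. The labels put them in 4 groups of 3: compound OB at 100 µM, compound PD at 3 nM, and a separate set of DMSO solvent controls for each compound. The labels do not say that the replicates of a group came from separate cultures or animals, so every p-value measures only the spread between these samples, which includes technical spread. The series also lists 2 chromatin samples, a CREB immunoprecipitation and its input, which are not analysed here.

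The values of each gene in each library are FPKM (fragments scaled to gene length and to the mapped fragments of the library), deposited by the authors with 2 decimals. RNA was extracted with a column kit and libraries were made with Illumina protocols, per the labels' protocols. Reads were aligned with STAR to mm10, per the submitters' processing notes. The STAR version, the program that made the FPKM values, the annotation, the use of strand and any selection of RNA with poly(A) tails are not given in the sources used here. Genes that overlap, antisense pairs and near-identical copies therefore have uncertain values. The 2 sets use different annotations, with 24054 genes listed in each library of the OB set and 54752 in each library of the PD set.

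In the OB set, 380 genes whose name had been split at a hyphen held displaced values and were left out, which leaves out the globin genes and the H2 genes of that set. The mitochondrially encoded genes are not listed in that set. Among the 33 such names with a mean of at least 5 FPKM, the median absolute log2 difference of compound OB replicates 2 and 3 from DMSO was 0.739, against 0.104 for 7910 other genes, while between DMSO replicates 2 and 3 it was 0.121 against 0.108. In each set 27 names that had turned into dates were left out. In the PD set 93 entries that repeated a symbol were left out. This left 23647 symbols in the OB set and 54632 in the PD set. Gene coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names.

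The sequencing depth is unknown, because FPKM values carry no counts. Low values were searched for steps of whole reads, and 7% of the ratios to a gene's smallest value in the OB set and 8.81% in the PD set were whole within 0.05, against 10% by chance. The ratios compare libraries, in which a read can stand for different FPKM. Whole reads therefore need not leave whole ratios, and the search decides nothing. Without counts no counting error can be given, and the precision of a value is the SD over its 3 libraries.

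Each compound was compared with its own DMSO controls with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean-variance trend and robust moderation, on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on this scale, which understates the change of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The difference between the 2 compounds' effects was tested in one fit of all 12 libraries with 4 group means, over genes listed in both sets. Compound, dose and set go together here. A difference between the compounds therefore cannot be told apart from one between the sets in cells, preparation or processing. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

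There were 29 gene lists. The pathway lists were early progenitor and self-renewal, erythroid differentiation, glucocorticoid receptor targets, CREB and immediate early targets, muscarinic receptor and cAMP pathway, cholesterol biosynthesis, amino acid response, endoplasmic reticulum chaperones, heat shock proteins, p53 targets, S phase and replication, G2 and mitosis, glycolysis and hypoxia response, oxidative stress (NRF2) targets, aryl hydrocarbon receptor targets, interferon response, STAT5 and cytokine targets, lysosome (TFEB) genes, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes and histone genes. Markers of hepatocytes, macrophages, neutrophils with granulocyte precursors, mast cells with basophils, megakaryocytes, lymphoid cells, and endothelial with stromal cells stood for other cells of fetal liver. Lists with at least 5 tested members (23 in the OB set, 26 in the PD set, 25 for the difference) were tested with camera on the log2 values at a preset correlation of 0.01, and again with a correlation estimated from the data and with fry. Camera compares a list with the other genes, and fry tests whether the members of a list move, on balance, one way. Members were also tested with p-values adjusted over the list alone.

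The lists, the tests, the thresholds, the rule for named genes and the alternatives not marked otherwise were set before the data were examined. The set test of the difference between compounds was added after the data were seen. The rule named, for each compound, up to 8 rises and 8 falls with an adjusted p under 0.05, a mean of at least 5 FPKM and no overlap between the groups, or, where none passed, the 5 genes of that level with the smallest p. It added up to 4 passing members of each list, and 16 genes to be given whatever their values: Chrm1 to Chrm5, Creb1, Crem, Kit, Gata1, Gata2, Klf1, Zfp36l2, Nr3c1, Myb, Hbb-bt and Hba-a1. Other genes are named as examples chosen after their values were seen.

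The replicate numbers in the labels were checked for pairing. In the OB set, libraries with the same number deviated together from their group means (Pearson r across genes 0.832, 0.434 and 0.652 for replicates 1, 2 and 3), and in these deviations each library correlated best, among the libraries of the other group, with the one of its own number. The numbers were therefore taken to pair these libraries, and values with the replicate number as a block are given where they change a call. The pairing comes from the values, since the labels do not say what a number stands for.

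The fits were tested on simulated data. The changed genes were drawn from those with a mean of at least 5 FPKM, so recovery of lower genes was not tested. Noise was drawn at the moderated spreads of the same fits, so recovery may be lower in the real data. Of genes changed 1.5-fold, 2-fold and 4-fold, the fit without the block recovered 23.9%, 80.6% and 98.5% in the OB set (10027 genes), 2.99%, 46.3% and 93.9% in the PD set (11574 genes), and the blocked fit of the OB set 95.5%, 100% and 100% (10037 genes). The test of the difference recovered 3.17%, 31.8% and 93.3% (9275 genes). In 20 simulated sets with no change at all, at least 1 gene was called in 5 sets without the block (at most 1 gene), in 17 sets with the block (at most 8, median 2.5) and in 8 sets simulated on the PD libraries (at most 2). The smallest adjusted p in them was 7.74e-04, 6.35e-11 and 9.36e-06, in that order. These fits therefore call genes more often than the threshold implies, and a small adjusted p alone does not secure a call. The set test found the list that had been moved, and called no other list, in all 4 simulated comparisons. The simulated genes varied independently of each other, so these comparisons cannot show false calls from members that vary together. In the real data the estimated correlation was 0.559 for histone genes in the OB set and 0.734 for megakaryocyte markers in the PD set.

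The alternatives were another pseudocount (0.1), no filter and a mean of at least 5, the replicate block, one fit of all 12 libraries, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were median-ratio scaling, quantile normalization, scaling to the total outside globins, moderation that is not robust, the split names as deposited, and leaving out each replicate pair of the OB set.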

Results

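The series asks which genes bear on the self-renewal of BFU-E, the erythroid progenitors that divide to keep their own number before they mature. Cultured BFU-E of C57BL/6 fetal liver were given compound OB at 100 µM or compound PD at 3 nM, and each compound has its own 3 DMSO control libraries. Over all genes the median log2 fold change was 0.03 after compound OB (5936 genes higher, 4168 lower) and 0.06 after compound PD (7032 higher, 4873 lower). With median-ratio scaling these were 0.00 (4979 higher and 5118 lower after compound OB) and −0.03 (5464 higher and 6426 lower after compound PD). With quantile normalization they were 0.00 (5014 higher, 5090 lower) and −0.03 (5389 higher, 6516 lower). Fold changes below are log2, compound minus DMSO, and values are FPKM.

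After compound OB, libraries compared within their replicate numbers gave 4 genes that rose and 3 that fell, while no gene passed when the 6 libraries were taken as independent. Mt2, a metal-binding metallothionein, rose from 122 ± 36.9 to 524 ± 146.5 (SD, n = 3; log2 2.10, SE 0.05, adjusted p = 1.23e-04 with the block; SE 0.29, adjusted p = 0.331 without). Pygl, the liver form of glycogen phosphorylase, rose from 4.80 ± 0.998 to 16.5 ± 1.855 (SD, n = 3; log2 1.60, SE 0.09, adjusted p = 0.013 with the block; SE 0.16, adjusted p = 0.114 without). Slc7a3, which carries cationic amino acids into the cell, rose from 2.65 ± 1.60 to 11.9 ± 3.22 (SD, n = 3; log2 1.89, SE 0.13, adjusted p = 0.0172 with the block; SE 0.35, adjusted p = 0.494 without). The uncharacterised 0610040J01Rik rose from 0.79 ± 0.324 to 3.82 ± 0.857 (SD, n = 3; log2 1.43, SE 0.09, adjusted p = 0.0172 with the block; SE 0.19, adjusted p = 0.329 without).

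The 3 falls were H1f0, Gm4070 and Dnaja4. H1f0, the linker histone H1.0 that builds up in cells leaving the cycle, fell from 58.9 ± 10.2 to 26.5 ± 5.59 (SD, n = 3; log2 −1.13, SE 0.08, adjusted p = 0.0172 with the block; SE 0.20, adjusted p = 0.494 without). Gm4070 fell from 7.60 ± 0.470 to 0.68 ± 0.462 (SD, n = 3; log2 −2.39, SE 0.17, adjusted p = 0.0181 with the block; SE 0.21, adjusted p = 0.109 without), and its family has near-identical copies, so its value is uncertain. Dnaja4, a co-chaperone of heat shock protein 70, fell from 17.2 ± 2.57 to 9.31 ± 1.78 (SD, n = 3; log2 −0.82, SE 0.07, adjusted p = 0.0433 with the block; SE 0.17, adjusted p = 0.584 without). In the GRCm38.p6 assembly the 7 genes lie at chromosome 8, 94172618 to 94173567 (Mt2), chromosome 12, 70190815 to 70227683 (Pygl), chromosome X, 101079146 to 101090452 (Slc7a3), chromosome 5, 63811657 to 63899626 (0610040J01Rik), chromosome 15, 79028212 to 79030504 (H1f0), chromosome 7, 105895118 to 105953967 (Gm4070) and chromosome 9, 54698848 to 54716317 (Dnaja4).

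Without the block, limma called 0 of 10104 genes after compound OB, with 372 at an unadjusted p under 0.05 against 505 by chance, and 882 genes had no overlap between groups (8.73%, against 10% by chance). With the block 7 genes were called, 1506 had an unadjusted p under 0.05, and the same fit called up to 8 genes in simulated sets in which nothing had changed. The smallest adjusted p in those simulated sets was 6.35e-11, below that of each of the 7 genes. The blocked count was 1126 without replicate 1, 147 without replicate 2 and 3 without replicate 3. Blocked fits without a pair have very few residual degrees of freedom, so these counts are unstable. The unblocked count was 14 (13 up, 1 down) without OB DMSO replicate 1 and 0 without any other library.

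The 5 genes with the smallest p and a mean of at least 5 FPKM were Pygl, Tph1, Hif3a, Mt2 and Pck2, and none passed without the block. Tph1, which makes the serotonin precursor, measured 136 ± 21.3 in DMSO and 356 ± 49.4 with compound OB (SD, n = 3; log2 1.39, SE 0.15, adjusted p = 0.177; 0.0636 with the block). Hif3a, a subunit of the hypoxia-inducible factors, measured 8.67 ± 0.70 and 23.3 ± 4.69 (SD, n = 3; log2 1.31, SE 0.15, adjusted p = 0.182; 0.0538 with the block). Pck2, the mitochondrial enzyme that makes phosphoenolpyruvate, measured 39.9 ± 1.58 and 61.2 ± 3.01 (SD, n = 3; log2 0.60, SE 0.09, adjusted p = 0.331; 0.0717 with the block). Kit, the receptor for stem cell factor, measured 24.0 ± 1.58 and 38.2 ± 3.09 (SD, n = 3; log2 0.64, SE 0.10, adjusted p = 0.494; 0.0892 with the block).

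**Figure D1:**
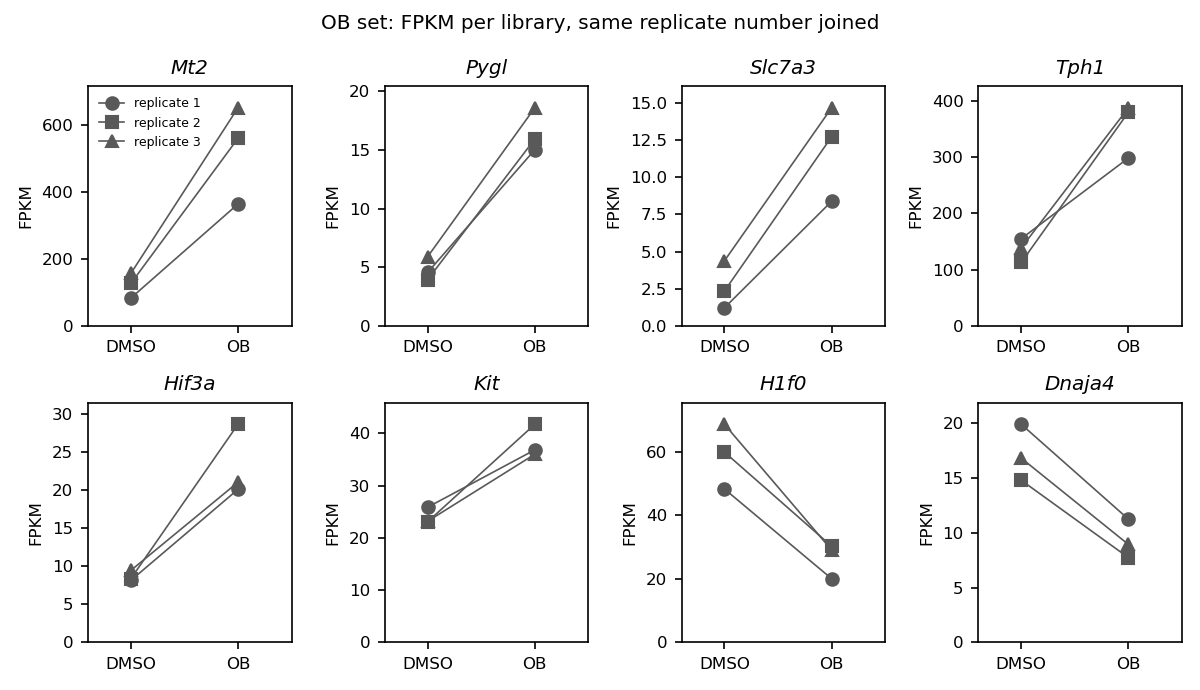
FPKM of 8 genes in each library of the OB set, with libraries of the same replicate number joined. Hif3a, Tph1 and Kit did not pass in either fit.

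The regulators of erythroid fate set for reporting had these values in the OB set. Gata1, the main erythroid transcription factor, measured 153 ± 28.3 in DMSO and 158 ± 14.1 with compound OB (SD, n = 3; log2 0.07), and Gata2, its progenitor counterpart, 28.2 ± 10.3 and 44.5 ± 8.96 (log2 0.68). Klf1 measured 241 ± 35.0 and 259 ± 20.2 (log2 0.11), Myb 42.2 ± 7.99 and 48.4 ± 8.55 (log2 0.20), Zfp36l2, an RNA-binding protein tied to BFU-E self-renewal, 36.6 ± 9.93 and 49.9 ± 4.77 (log2 0.46), and the glucocorticoid receptor Nr3c1 14.4 ± 3.06 and 17.8 ± 3.51 (log2 0.29; SD, n = 3 throughout). Creb1 measured 10.6 ± 3.32 and 10.3 ± 2.29 (log2 −0.01) and Crem 8.33 ± 1.33 and 6.82 ± 0.519 (log2 −0.25; SD, n = 3). The muscarinic receptor Chrm4 measured 1.36 ± 0.738 and 0.92 ± 0.414 (SD, n = 3; log2 −0.28), and each of these 9 genes had an adjusted p of 1.00. Chrm1 ranged from 0.01 to 0.05 and Chrm3 reached at most 0.02, both under the filter, Chrm2 and Chrm5 were listed at 0, and Hbb-bt and Hba-a1 are not used in this set.

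Amino acid response genes, which cells turn on through ATF4 when amino acids run short, were higher after compound OB in 34 of 35 members (median log2 0.29, camera adjusted p = 2.91e-15). With an estimated correlation the adjusted p = 0.269. Adjusted over the list alone 5 members rose, against 0 over all genes: the folate-pathway enzyme Shmt2 (194 ± 10.1 to 274 ± 16.6, log2 0.50), Slc7a3, the pseudokinase Trib3 (94.5 ± 4.21 to 124 ± 2.86, log2 0.39), the transporter chain Slc3a2 (105 ± 7.69 to 143.5 ± 7.47, log2 0.45) and Chac1, which breaks down glutathione (9.91 ± 1.53 to 16.1 ± 1.33, log2 0.66; SD, n = 3). With the block 22 rose over the list alone and 1, Slc7a3, over all genes (camera adjusted p = 3.94e-16). The 5 became 0 without OB DMSO replicate 2 or compound OB replicate 2 and 11 without OB DMSO replicate 1, and the 22 became 14 without replicate 3.

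Glucocorticoid receptor targets, whose induction by steroids keeps BFU-E dividing, had a median log2 of 0.14 with 14 of 19 members higher (camera adjusted p = 0.0027; adjusted p = 0.827 with an estimated correlation). Mt1 (744 ± 122 to 1205 ± 84.3, log2 0.70) and Mt2 rose over the list alone, against 0 over all genes (SD, n = 3). With the block 8 members rose over the list alone, among them Fkbp5 (7.34 ± 1.41 to 10.9 ± 0.947, log2 0.52) and the clock gene Per1 (log2 0.59), and Txnip fell, against 1 over all genes, Mt2. The list had a median of 0.07 (adjusted p = 0.114) without compound OB replicate 1, 0.37 without OB DMSO replicate 1, 0.04 (12 of 19 higher) without OB DMSO replicate 2 and 0.23 without compound OB replicate 2. Further, 7 members rose over the list alone without OB DMSO replicate 1 and 1 without compound OB replicate 3, and the 8 became 2 without replicate 3.

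Early progenitor and self-renewal genes were higher in 17 of 22 members (median log2 0.13, camera adjusted p = 0.0209; adjusted p = 0.827 with an estimated correlation). Kit rose over the list alone, against 0 over all genes. With the block 7 rose over the list alone, namely Kit, Myc (76.4 ± 7.71 to 101.1 ± 9.23, SD, n = 3), Il1rl1, Gata2, Zfp36l2, Nr3c1 and Myb, against 0 over all genes, and this was 0 without replicate 3. The call of the list was lost without OB DMSO replicate 3 (median 0.10, adjusted p = 0.146) and without compound OB replicate 1 (0.09, adjusted p = 0.154). The median was 0.28 without OB DMSO replicate 1 and 0.03 (14 of 22 higher) without OB DMSO replicate 2. Kit alone did not pass without OB DMSO replicate 2, OB DMSO replicate 3 or compound OB replicate 2, and 7 members rose without OB DMSO replicate 1.

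Histone transcripts, most of which lack poly(A) tails and are made in S phase, were lower after compound OB in 60 of 64 members (median log2 −1.07, camera adjusted p = 9.84e-20; adjusted p = 0.827 with an estimated correlation). This rests on OB DMSO replicate 2, whose histone median was log2 4.93 against 1.40 to 2.04 in the other 5 libraries. The same library held Rn45s, the ribosomal RNA precursor, at 12380 (175 to 955 in the others), Rmrp at 2069 (11.2 to 51.5) and Rpph1 at 1285 (11 to 44.8). Without it the histone median was −0.15 with 44 of 64 members lower (adjusted p = 0.00269). Over the list alone H1f0 fell, against 0 over all genes. Without OB DMSO replicate 1, 2 members fell and 1 rose, and no member passed without any other library. With the block 4 fell over the list alone (H1f0, Hist1h1c, Hist1h4i and Hist2h2aa2), against 1 over all genes, and 11 fell without replicate 2 (median −0.29). Single histone genes have near-identical copies and their values are uncertain.

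**Figure D2:**
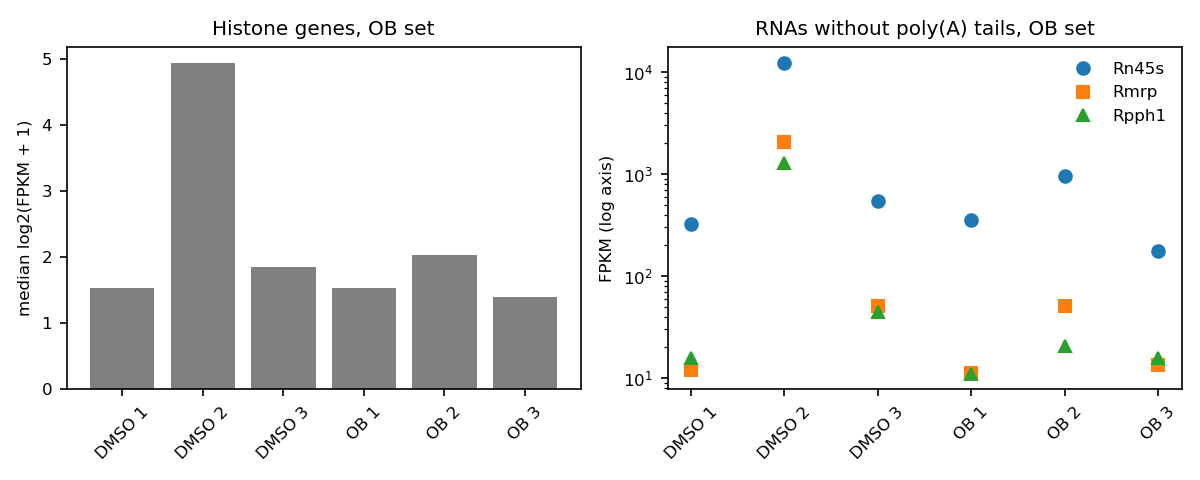
Median log2 of the histone genes, and FPKM of Rn45s, Rmrp and Rpph1 on a log axis, in each library of the OB set. OB DMSO replicate 2 stands apart in all 4.

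Cholesterol biosynthesis genes, the sterol pathway that SREBP2 controls, were lower in 20 of 25 members (median log2 −0.12, camera adjusted p = 3.51e-06; adjusted p = 0.727 with an estimated correlation). The median was −0.21 without OB DMSO replicate 1 and −0.07 without OB DMSO replicate 3. No member passed over the list alone without the block. With it 9 fell over the list alone and 0 over all genes, among them Idi1 (265 ± 6.04 to 224 ± 16.45, log2 −0.25) and Fdps (718 ± 81.7 to 616 ± 60.7, log2 −0.22; SD, n = 3), and the 9 became 4 without replicate 2 and 0 without replicate 3.

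Glycolysis and hypoxia response genes were lower in 27 of 34 members (median log2 −0.17, camera adjusted p = 1.28e-04; adjusted p = 0.827 with an estimated correlation). With the block 8 fell over the list alone, among them the pyruvate kinase Pkm (503.5 ± 119 to 283 ± 39.3, log2 −0.81) and the lactate dehydrogenase Ldha (1235 ± 315 to 918 ± 99.9, log2 −0.40), and 2 rose, Hk1 and the oxygen sensor Egln3 (7.98 ± 4.44 to 23.2 ± 7.23, log2 1.52; SD, n = 3), against 0 over all genes. Without the block 0 passed over the list alone, but 13 fell and 4 rose without OB DMSO replicate 1. The call was lost without OB DMSO replicate 3 (median −0.03, adjusted p = 0.0743), the median was −0.33 without OB DMSO replicate 1 and −0.09 without compound OB replicate 1, and the blocked counts were 20 falls without replicate 1, 4 without replicate 2 and 1 without replicate 3.

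The p53 targets (median log2 −0.12, 22 of 31 lower, camera adjusted p = 0.0171; adjusted p = 0.906 with an estimated correlation) turned to a median of 0.14 (adjusted p = 0.786) without OB DMSO replicate 1. That library held Cdkn1a, the cell cycle inhibitor p21, at 321 against 76.1 and 81.9 in the other DMSO libraries. The p53 call was also lost without compound OB replicate 2 (−0.03, adjusted p = 0.511) and replicate 3 (−0.02, adjusted p = 0.251), and with the block 8 members fell and Plk3 rose over the list alone, against 0 over all genes, with no fall without replicate 3. Oxidative phosphorylation genes had a median of −0.02 and a mean of 0.01, opposite in sign (48 of 82 lower, camera adjusted p = 0.0401; adjusted p = 0.906 with an estimated correlation). That call was lost without OB DMSO replicate 1 (0.00, adjusted p = 0.168), OB DMSO replicate 3 (0.01, adjusted p = 0.559) or compound OB replicate 2 (0.00, adjusted p = 0.865). It stayed with median-ratio scaling (median −0.05, camera adjusted p = 0.00148).

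The other lists of the OB set were not called. Erythroid differentiation genes had a median log2 of 0.09 with 34 of 48 higher (adjusted p = 0.252), CREB and immediate early targets 0.09 (0.675), the muscarinic receptor and cAMP pathway 0.07 (0.561), STAT5 and cytokine targets 0.08 (0.0615) and oxidative stress (NRF2) targets 0.09 (0.312). Endoplasmic reticulum chaperones had 0.01 (0.561), heat shock proteins −0.01 (0.368), S phase and replication genes 0.02 (0.648), G2 and mitosis genes −0.04 (0.138; 0.0147 with the block) and the interferon response −0.08 (0.207). Mast cell and basophil markers had −0.23 (0.490). The median was positive but the test pointed down for lysosome (TFEB) genes (0.03, 0.481), cytosolic ribosomal proteins (0.01, 0.561), neutrophil and granulocyte precursor markers (0.09, 0.675) and megakaryocyte markers (0.05, 0.664). Too few members passed the filter for aryl hydrocarbon receptor targets (2), hepatocyte (1), macrophage (3), lymphoid (1) and endothelial and stromal markers (3), and the mitochondrially encoded genes are not listed in this set. With the block some members passed over the list alone, against 0 over all genes: 3 rose for STAT5 and cytokine targets (Id1, Socs1, Spry1), 3 rose and 1 fell for CREB and immediate early targets (Nr3c1, Per1 and Per2; Ier3). Likewise 2 rose and 1 fell for erythroid differentiation (Aqp1 and Isg20; Car2) and for NRF2 targets (Cat and Hmox1; Prdx1). For the interferon response 1 rose and 1 fell (Isg20; Isg15), and Nqo1 rose of the 2 aryl hydrocarbon receptor targets. All of these counts were 0 without replicate 3. With median-ratio scaling and no block, STAT5 and cytokine targets were called (median 0.06, adjusted p = 0.0430) and the p53 call was lost (0.0533). Without replicate 1, 6 rose and 3 fell for erythroid differentiation, 8 rose and 1 fell for CREB targets, 7 rose and 2 fell for NRF2 targets, 5 rose for STAT5 targets and Nqo1 did not pass. Without replicate 2, 2 rose and 4 fell for CREB targets, 1 rose and 1 fell for NRF2 targets, and 1 rose and 3 fell for the interferon response. With all libraries, the block and median-ratio scaling, 4 rose and 6 fell for CREB targets and 1 rose and 3 fell for the interferon response. In that fit 3 rose and 0 fell for erythroid differentiation, and 4 rose and 0 fell for STAT5 targets.

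Several of these lists were called once a library was left out. Megakaryocyte markers had a median of 0.47 (adjusted p = 1.71e-04) without OB DMSO replicate 1 and −0.20 (0.0187), −0.08 (0.0251) and −0.14 (0.00928) without OB DMSO replicate 2, OB DMSO replicate 3 and compound OB replicate 1. Neutrophil markers had 0.57 (0.0331) without OB DMSO replicate 1, −0.18 (0.0356) without OB DMSO replicate 3 and −0.35 (0.00257) without compound OB replicate 1. The interferon response was called without OB DMSO replicate 3 (adjusted p = 0.00152), OB DMSO replicate 2 (0.0195) or compound OB replicate 1 (8.01e-05), and G2 and mitosis genes without OB DMSO replicate 1 (8.74e-05) or compound OB replicate 3 (0.0192). Erythroid differentiation genes were called without compound OB replicate 2 (0.0359) or 3 (0.0254), and oxidative stress (NRF2) targets without compound OB replicate 2 (0.0438) or 3 (0.0499). S phase and replication genes were called without OB DMSO replicate 3 (0.0302) or compound OB replicate 1 (0.0285). STAT5 and cytokine targets were called without OB DMSO replicate 1 (0.0249) or compound OB replicate 2 (0.0472) or 3 (0.0179), and the muscarinic receptor and cAMP pathway without OB DMSO replicate 1 (0.0449). Lysosome (TFEB) genes were called without OB DMSO replicate 2 (median −0.08, 0.0269), and ribosomal proteins without OB DMSO replicate 3 (0.05, 0.0352) or compound OB replicate 3 (−0.02, 0.0310). In both groups replicate 1 stood apart, with the adhesion protein Zyx at 58.1 in DMSO and 41.7 with compound OB, against 8.88 and 10.4 in the other DMSO libraries and 18.3 and 13.8 in the other treated ones.

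After compound PD, 2 genes rose and 2 fell. Fcnb, a ficolin of granulocyte precursors, rose from 83.2 ± 7.74 to 241 ± 25.6 (SD, n = 3; log2 1.52, SE 0.15, adjusted p = 0.0137). Ndrg2, a stress-responsive gene of the N-myc downstream-regulated family, fell from 39.1 ± 3.96 to 14.3 ± 0.143 (SD, n = 3; log2 −1.38, SE 0.16, adjusted p = 0.0336). Rnu3a, a U3 small nucleolar RNA with near-identical copies and so of uncertain value, is listed at 0 in the 3 DMSO libraries and at 16.26, 20.5 and 12.42 with compound PD (adjusted p = 6.87e-04). Gm26712, which has no coordinates in the reference used, was at 9.79, 23.68 and 9.19 in DMSO and is listed at 0 in the 3 treated libraries (adjusted p = 0.012). Fcnb lies at chromosome 2, 28076479 to 28084910, Ndrg2 at chromosome 14, 51905271 to 51914004, and Rnu3a at chromosome 10, 40258468 to 40258679.

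In the PD set limma called 4 of 11905 genes (2 up, 2 down), and 1269 had an unadjusted p under 0.05 (1077 up, 192 down) against 595 by chance. The called genes were 2 up and 1 down with median-ratio scaling or quantile normalization, and 4 up and 2 down with scaling to the total outside globins. No overlap between groups was seen for 2002 genes (16.8%, against 10% by chance). The count was 168 (132 up, 36 down) without PD DMSO replicate 1, 2 without PD DMSO replicate 2, 4 without PD DMSO replicate 3 and 1 without each compound PD library. Fcnb had an adjusted p = 0.0649 without PD DMSO replicate 2 and 0.0939 to 0.157 without a compound PD library. Ndrg2 had 0.0649 and 0.1002 without PD DMSO replicate 2 and 3 and 0.157 to 0.290 without a compound PD library. Gm26712 had 0.145, 0.0551 and 0.0668 without compound PD replicates 1, 2 and 3. In simulated sets with no change the same fit called up to 2 genes. The smallest adjusted p there was 9.36e-06, below that of each of the 4 genes called here.

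**Figure D3:**
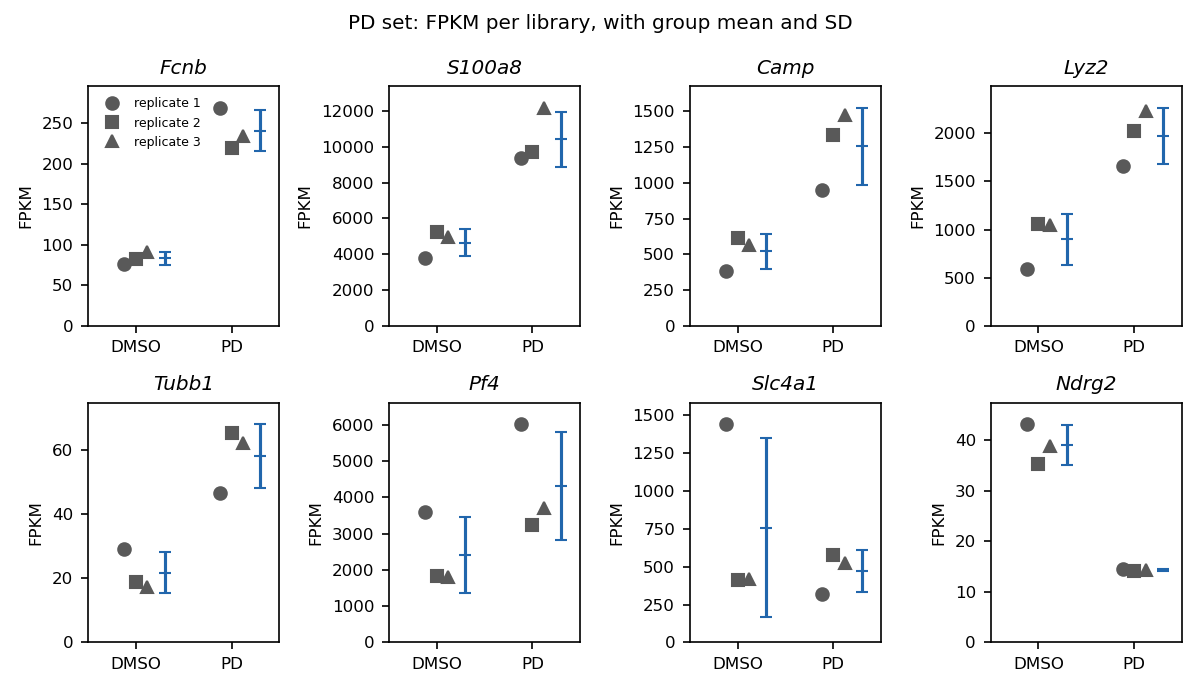
FPKM of 8 genes in each library of the PD set, with mean and SD of each group. Only Fcnb and Ndrg2 passed over all genes without the replicate block, and S100a8, Camp, Lyz2 and Pf4 passed as well with it.

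The genes set for reporting had these values in the PD set, none passing. Kit measured 21.6 ± 1.15 in DMSO and 32.4 ± 7.70 with compound PD (SD, n = 3; log2 0.54, adjusted p = 0.351), and Gata2 48.8 ± 10.3 and 66.0 ± 21.8 (SD, n = 3; log2 0.40, adjusted p = 0.690). The log2 fold changes were −0.03 for Gata1 (adjusted p = 0.976), −0.29 for Klf1 (0.637), 0.24 for Zfp36l2 (0.788), 0.11 for Nr3c1 (0.934), 0.16 for Myb (0.956) and 0.00 for Creb1 (0.998). Crem measured 44.5 ± 31.9 and 25.5 ± 2.15 (SD, n = 3; log2 −0.56, adjusted p = 0.742), with 80.9 in PD DMSO replicate 1. Among the globins, Hbb-bt had log2 −0.40 (adjusted p = 0.816) and Hba-a1, which has a near-identical neighbour, log2 −0.31 (0.847). All 5 muscarinic receptors were under the filter, with Chrm4 reaching 1.55 and Chrm1 1.18 in a single library.

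Markers of neutrophils and granulocyte precursors, cells of another lineage of the fetal liver, were higher after compound PD in 19 of 19 members (median log2 0.92, camera adjusted p = 1.23e-14; adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone 14 rose, against 1 over all genes, Fcnb. Among them the calgranulins S100a8 (4650 ± 759 to 10410 ± 1536, log2 1.17) and S100a9 (6852 ± 1488 to 15350 ± 2209, log2 1.18), the antimicrobial Camp (521 ± 121 to 1255 ± 270, log2 1.27) and the iron-scavenger Lcn2 (419 ± 113 to 890 ± 166, log2 1.11) are granule or cytosol proteins of neutrophils (SD, n = 3). The early granule enzymes Mpo (log2 0.15) and Ctsg (log2 0.03) did not pass. Without each library in turn, 12 to 14 members rose over the list alone.

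Macrophage markers were higher in 7 of 8 members (median log2 0.97, camera adjusted p = 2.68e-05; adjusted p = 0.427 with an estimated correlation). Over the list alone 6 rose, against 0 over all genes: Adgre1, Csf1r, Hpgd, Mpeg1 (14.5 ± 4.53 to 31.0 ± 6.37, log2 1.07), the cathepsin Ctss (2.81 ± 0.230 to 10.5 ± 2.58, log2 1.57) and the lysozyme Lyz2 (898 ± 264 to 1971 ± 293, log2 1.17; SD, n = 3). These 6 became 4 without PD DMSO replicate 1, compound PD replicate 1 or compound PD replicate 2, and 5 without any other library. Megakaryocyte markers were higher in 21 of 21 members (median log2 0.86, camera adjusted p = 4.27e-13; adjusted p = 0.455 with an estimated correlation). Over the list alone 18 rose, against 0 over all genes, among them the platelet tubulin Tubb1 (21.75 ± 6.44 to 57.9 ± 9.99, log2 1.39), the integrin Itga2b (253 ± 76.7 to 414 ± 90.5, log2 0.73) and the chemokine Pf4 (2411 ± 1036 to 4322 ± 1488, log2 0.87; SD, n = 3). The 18 became 1 with median-ratio scaling or without PD DMSO replicate 2, PD DMSO replicate 3 or compound PD replicate 1.

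Erythroid differentiation genes were lower in 50 of 55 members (median log2 −0.39, camera adjusted p = 5.17e-13; adjusted p = 0.515 with an estimated correlation), and 0 passed over the list alone or over all genes. The red cell anion exchanger Slc4a1 measured 757 ± 592 in DMSO and 475 ± 139 with compound PD (SD, n = 3; log2 −0.45), and the heme enzyme Alas2 had log2 −0.41. PD DMSO replicate 1 held Slc4a1 at 1441 against 412 and 419 in the other DMSO libraries, Alas2 at 1126 against 382 and 376, and globins at 32.32% of FPKM against 16.57% and 17.65%. Without that library the erythroid median was −0.09 (adjusted p = 0.176), and without compound PD replicate 1 it was −0.19 (adjusted p = 3.98e-06).

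Cytosolic ribosomal proteins, whose values are uncertain because processed copies abound, were lower in 83 of 84 members (median log2 −0.15, camera adjusted p = 2.01e-14; adjusted p = 0.515 with an estimated correlation). Rplp0 measured 2680 ± 81.7 and 2316 ± 126 (SD, n = 3; log2 −0.21), and 0 members passed over the list alone, but 21 fell without PD DMSO replicate 1, and the median was −0.24 with median-ratio scaling. Amino acid response genes were lower in 30 of 35 members (median −0.19, camera adjusted p = 1.94e-05; adjusted p = 0.427 with an estimated correlation), with a median of −0.13 (0.0632) without PD DMSO replicate 1 and −0.07 (23 of 35 lower, 0.00912) without compound PD replicate 1. S phase and replication genes were lower in 40 of 56 (median −0.08, camera adjusted p = 4.52e-04; adjusted p = 0.698 with an estimated correlation), with −0.02 (0.117) without compound PD replicate 1 and 0.00 (0.0526) without PD DMSO replicate 2, while without PD DMSO replicate 1 it was −0.25 and 4 members fell over the list alone. Without PD DMSO replicate 3 the S phase median was 0.00 (0.0271), without compound PD replicate 3 it was −0.12, and with median-ratio scaling −0.17 (51 of 56 lower). The aryl hydrocarbon receptor targets were lower in 4 of 5 (median −0.34, camera adjusted p = 0.0307; adjusted p = 0.515 with an estimated correlation), with an adjusted p = 0.0700 without PD DMSO replicate 1, 0.174 without PD DMSO replicate 3 and 0.0718 without compound PD replicate 2. The p53 targets had a median of −0.08 (18 of 33 lower, camera adjusted p = 0.0307; adjusted p = 0.455 with an estimated correlation), which turned to 0.05 (0.958) without PD DMSO replicate 1 and was 0.05 (0.240) without compound PD replicate 1.

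Interferon response genes were higher in 23 of 26 members (median log2 0.33, camera adjusted p = 0.00442; adjusted p = 0.515 with an estimated correlation). The RNA sensor Ddx58 (2.31 ± 0.216 to 5.62 ± 0.643; SD, n = 3) rose over the list alone, against 0 over all genes, and this count was 5 without PD DMSO replicate 1, 2 without compound PD replicate 1, and 0 without any other library or with median-ratio scaling. The interferon call was lost without PD DMSO replicate 2 (0.0591), PD DMSO replicate 3 (0.135), compound PD replicate 2 (0.0718) or compound PD replicate 3 (0.0669). Endoplasmic reticulum chaperones were higher in 23 of 24 (median 0.22, camera adjusted p = 0.011; adjusted p = 0.698 with an estimated correlation), with an adjusted p = 0.400 without compound PD replicate 1 and 0.0936 without PD DMSO replicate 3. Lysosome (TFEB) genes were higher in 24 of 28 (median 0.18, camera adjusted p = 0.0366; adjusted p = 0.662 with an estimated correlation), with an adjusted p = 0.0510 without PD DMSO replicate 2, 0.0953 without PD DMSO replicate 3 and 0.0718 without compound PD replicate 2. Median-ratio scaling made the chaperone median 0.13 and the lysosome median 0.09 (21 of 28 higher).

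The other lists of the PD set were not called. Early progenitor and self-renewal genes had a median log2 of 0.25 with 19 of 26 higher (adjusted p = 0.158), CREB and immediate early targets 0.20 (0.201), the muscarinic receptor and cAMP pathway 0.19 (0.104), mast cell and basophil markers 0.30 (0.119) and histone genes 0.13 (0.718). Glycolysis and hypoxia response genes had 0.24 (0.104), with Pkm (215 ± 14.4 to 364 ± 76.3) and the lactate transporter Slc16a3 (11.3 ± 0.687 to 22.8 ± 2.29) rising over the list alone, against 0 over all genes (SD, n = 3). These 2 became 0 without PD DMSO replicate 2 or compound PD replicate 1, 1 without PD DMSO replicate 1, PD DMSO replicate 3 or compound PD replicate 3, and 3 without compound PD replicate 2. STAT5 and cytokine targets had 0.03 (0.483), with Id2 (35.8 ± 4.93 to 63.2 ± 6.21) and Osm (4.48 ± 0.689 to 11.5 ± 4.19) rising over the list alone, against 0 over all genes (SD, n = 3). These 2 became 0 without PD DMSO replicate 2, compound PD replicate 2 or compound PD replicate 3 and with median-ratio scaling, 1 without compound PD replicate 1, and 3 without PD DMSO replicate 1 or 3. Cholesterol biosynthesis genes had −0.07 (0.127), heat shock proteins −0.07 (0.0801), oxidative stress (NRF2) targets −0.10 (0.0803), oxidative phosphorylation −0.03 (0.0669) and mitochondrially encoded genes 0.05 (0.824). The median was positive but the test pointed down for glucocorticoid receptor targets (0.12, 0.973), of which Lcn2 rose over the list alone against 0 over all genes (none without PD DMSO replicate 2, compound PD replicate 2 or compound PD replicate 3), and for G2 and mitosis genes (0.04, 0.780). With median-ratio scaling oxidative phosphorylation (median −0.12, 65 of 80 lower, adjusted p = 5.52e-04) and heat shock proteins (−0.16, 0.0248) were called and the p53 call was lost (0.0583). Too few hepatocyte (1), lymphoid (2) and endothelial and stromal markers (4) passed the filter.

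Without PD DMSO replicate 1 the heat shock proteins (median −0.32, 11 falls over the list alone, adjusted p = 1.36e-06), STAT5 and cytokine targets (0.00381), oxidative phosphorylation (0.00427), CREB and immediate early targets (0.0147) and the muscarinic receptor and cAMP pathway (0.0213) were called. Early progenitor genes (0.0420), glycolysis genes (0.0436), the muscarinic receptor and cAMP pathway (0.0464) and mast cell markers (0.0417) were called without compound PD replicate 3, mast cell markers also without compound PD replicate 2 (0.0336). Oxidative phosphorylation (0.0116) and oxidative stress (NRF2) targets (0.0422) were likewise called without compound PD replicate 3, the latter also without PD DMSO replicate 2 (0.0288) or 3 (0.0425), and cholesterol biosynthesis without PD DMSO replicate 2 (0.0288) or replicate 3 (0.0327). PD DMSO replicate 1 also held Myb at 17.7 against 47.3 and 44.4 in the other DMSO libraries.

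**Figure D4:**
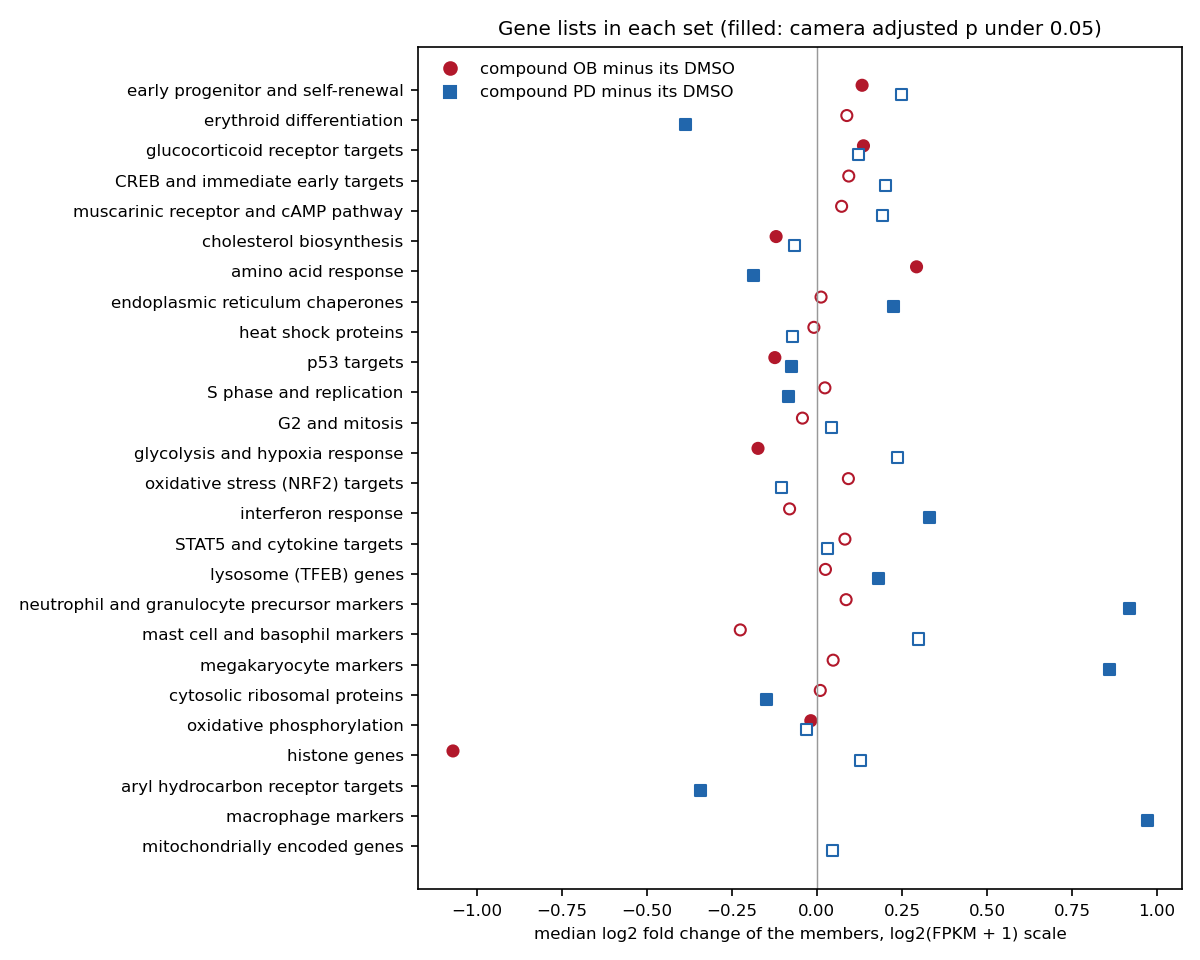
Median log2 fold change of each gene list after compound OB and after compound PD. Filled points have a camera adjusted p under 0.05 at the preset correlation.

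Between the 2 compounds, no single gene was called as different in its response (limma, 10353 genes tested, 0 different, 765 at an unadjusted p under 0.05). In simulated data, with changed genes of at least 5 FPKM in the OB set, this test recovered 3.17% of 1.5-fold and 31.8% of 2-fold differences. It therefore misses most differences of that size. The smallest adjusted p was 0.0992, shared by 6 genes that include Pkm (log2 −0.81 after compound OB, 0.73 after compound PD), Ctss (1.57 after compound PD) and the water channel Aqp9. The count was 15 (7 up, 8 down) without PD DMSO replicate 1, 4 without PD DMSO replicate 2, 1 without PD DMSO replicate 3 and 0 without any other library. No gene of the 9295 tested in both was called in both, which follows from the 0 calls after compound OB, so there was no overlap to test. With the block the counts were 3 up and 3 down after compound OB among these genes, and again none was shared, with at most 0.00678 per direction expected by chance. Across these genes, which are not independent replicates, the fold changes had Pearson r = 0.02 and Spearman 0.068, and 54.5% had the same sign. At an unadjusted p under 0.05 in both, 27 genes were found, 17 with the same sign. No level expected by chance was computed for these counts. The same holds for the share of the same sign, which rises where most genes are higher in both sets.

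Among the gene lists 12 differed between the compounds, 4 higher with compound OB and 8 lower. Chance is not excluded for that number, since 45 of 100 drawn splits of the libraries, the real one among them, gave at least 12 lists. Each compound has its own set, so these differences cannot be told apart from differences between the sets. Amino acid response genes, higher after compound OB and lower after compound PD, differed by a median log2 of 0.49 (camera adjusted p = 4.58e-15), and this list alone passed with an estimated correlation (adjusted p = 0.0275). That adjusted p ranged from 0.0128 to 0.332 over the fits without each library, and was 0.152 without OB DMSO replicate 1, 0.0543 without compound OB replicate 3, 0.332 without PD DMSO replicate 1, 0.0667 without compound PD replicate 1 and 0.0501 without compound PD replicate 3. Megakaryocyte (−0.81), macrophage (−1.24) and neutrophil and granulocyte precursor markers (−0.92) were lower with compound OB than with compound PD. Without OB DMSO replicate 1 these differences were −0.30 (camera adjusted p = 0.0148), −0.88 (3.19e-05) and −0.52 (0.00888). The test of the difference used 6 macrophage and 18 neutrophil markers, of which list only 3 and 13 members passed the filter in the OB set alone.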

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

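The set test of the difference between the compounds, and the tests of causes for the 3 patterns weighed below, were chosen after the results were seen, as were the splits of the lists that part the replicate pairs. The 12 lists named next are given because camera called their difference between the compounds.

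Amino acid response genes had a higher log2 fold change in the OB set than in the PD set (median over the list's genes of the difference 0.4857, camera adjusted p = 4.58e-15, and 0.0275 with an estimated correlation). The other 11 lists, given by the same median, had an adjusted p of 0.186 to 0.694 with an estimated correlation. Cytosolic ribosomal proteins differed by 0.1538 (camera adjusted p = 5.98e-13), erythroid differentiation genes by 0.4364 (5.59e-12) and S phase and replication genes by 0.1228 (8.53e-04). Markers of macrophages differed by −1.24 (7.29e-07), of neutrophils and granulocyte precursors by −0.9177 (2.28e-06) and of megakaryocytes by −0.8125 (2.5e-06). The filter here was the mean over all 12 libraries, which kept 6 macrophage and 18 neutrophil markers. In the OB set alone 3 and 13 passed. The scale understates changes of genes that are low in the OB set, so these 2 differences lean on the PD set. Histone genes differed by −1.0916 (5.95e-09), glycolysis and hypoxia response genes by −0.4718 (0.0014), the interferon response by −0.3821 (0.00276), endoplasmic reticulum chaperones by −0.1849 (0.0393) and lysosome (TFEB) genes by −0.171 (0.0403).

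Single libraries carry several of these differences. The histone difference was −0.26 (adjusted p = 0.272) without OB DMSO replicate 2, and the erythroid difference 0.23 (0.0571) without PD DMSO replicate 1. Glycolysis genes had an adjusted p = 0.0751 without OB DMSO replicate 3. S phase genes had 0.163 without OB DMSO replicate 1 and 0.102 without compound PD replicate 1, and the interferon response 0.129 without OB DMSO replicate 1, 0.0534 without PD DMSO replicate 2 and 0.0921 without PD DMSO replicate 3. Endoplasmic reticulum chaperones had 0.0584 with the replicate block, 0.0758 without OB DMSO replicate 3, 0.114 without compound OB replicate 1, 0.0897 and 0.141 without PD DMSO replicates 2 and 3, and 0.559 without compound PD replicate 1. Lysosome genes had 0.0506 with the block, 0.361 without OB DMSO replicate 1, 0.0944 and 0.0852 without compound OB replicates 2 and 3, 0.0534 and 0.0878 without PD DMSO replicates 2 and 3, and 0.0514 and 0.0696 without compound PD replicates 1 and 2. Megakaryocyte and neutrophil markers stayed called without OB DMSO replicate 1, with smaller differences of −0.30 and −0.52.

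The neutrophil markers higher after compound PD may reflect the cells present or the genes they express. PD DMSO replicate 1 is not the whole cause, since without it the median log2 was 0.6958 (camera adjusted p = 9.29e-11). Fewer erythroid cells, raising markers of every other cell type alike, stays open: neutrophil markers had a mean of 0.822 (SD 0.387 over 19 genes) and mast cell and basophil markers 0.234 (SD 0.770 over 14 genes), with a two-sided permutation p = 0.00359 over genes, which are not independent replicates, but macrophage (median 0.97) and megakaryocyte markers (0.86) were as high as neutrophil markers (0.92). A larger share of granulocyte-lineage cells predicts that members move by about the same factor, and their SD of 0.387, with a range from 0.03 (Ctsg) to 1.52 (Fcnb), lies between the bounds set for and against it, so this stays open. The labels say only that BFU-E were isolated and name no gate, every one of the 19 genes had a mean of at least 5 FPKM, and a response of the same cells to compound PD was not tested.

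Whether the erythroid genes lower after compound PD reflect the compound stays open. The median log2 of −0.39 over all libraries was −0.0942 (camera adjusted p = 0.176) without PD DMSO replicate 1 and −0.19 (3.98e-06) without compound PD replicate 1. PD DMSO replicate 1 was picked because it stands apart, with globins at 32.32% of FPKM and Mcpt8, a basophil protease, at 2.63 against 27.96 and 31.05 in the other DMSO libraries. Leaving it out had to bring the list nearer to 0, so this shows how far the median depends on that library and not why the library differs. No biological explanation was tested.

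Most of the fall in histone transcripts after compound OB rests on OB DMSO replicate 2. Without that library, picked because it stands apart, the same members had a median log2 of −0.1472 with 44 of 64 lower. Rn45s, Rmrp and Rpph1, which like most histone transcripts lack poly(A) tails, were highest in the same library, so more of such RNA there could be the cause, but how its RNA was selected is not given. Fewer cells in S phase as the cause of the median of −1.07 predicts lower S phase and replication genes. These had a median log2 of 0.0236 with 34 of 56 higher, and −0.05 to 0.10 without each library in turn. All genes had a median of 0.0297. With median-ratio scaling the list had −0.0112, with 26 higher and 30 lower, which lies between the bounds set for and against this cause. Of the S phase values, only the unscaled one argues against it. The histone medians also argue against it as the cause of the −1.07. OB DMSO replicates 1 and 3 had log2 1.53 and 1.85, within the 1.40 to 2.04 of the compound OB libraries. A part of fewer S phase cells in the smaller −0.1472 stays open. H1f0, a histone gene of polyadenylated transcripts, measured 26.5 with compound OB against 58.9 in DMSO and is a separate case.

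The real grouping was compared with the other ways to split the libraries. With 10 splits of 6 libraries, or 4 that part all replicate pairs, no share under 0.05 can be reached. After compound OB the real count of genes is 0, so all 10 splits reach it and the comparison tests nothing, but the highest other gave 794 by setting OB DMSO replicate 1, compound OB replicate 1 and compound OB replicate 2 apart, which points to structure between the samples beyond the compound. For the OB lists 6 of 10 splits gave at least the real 8, and the highest other gave 18, but splits that leave a replicate pair on one side take up the differences between replicates. Among the 4 that part all pairs, only the real 1 gave 8, and the others gave 4 to 6. With the replicate block, 1 of 4 splits gave 7 genes, the real one, and the highest other gave 0. After compound PD 1 of 10 splits gave at least the real 4 genes (highest other 1), and 4 of 10 gave at least the real 12 lists (highest other 15). For the difference between compounds the real count of genes is again 0, which 100 of 100 drawn splits reach whatever they show (highest other 24), and 45 of 100 gave at least the real 12 lists (highest other 19). With the OB pairs parted, 30 of 80 splits gave at least 12 lists (highest other 19), so chance is not excluded for that number of lists.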

How the results depend on the processing

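The count of genes called after compound OB was 0, and with the replicate block 7, or 6 when moderation was not robust. It was 105 with the block and median-ratio scaling, 1 in a fit of all 12 libraries, and 1, or 21 with the block, with the split names as deposited. Without each library in turn it ranged from 0 to 14. With the block it was 1126, 147 and 3 without replicates 1, 2 and 3. Why these counts are so far apart was not tested. Without a replicate pair the blocked fit has very few residual degrees of freedom per gene. Its count then leans on the spread shared across genes and does not measure the size of an effect. The block changed no other call of the OB set than those given with it.

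The count after compound PD was 4. It was 1 without a filter on low values, 33 in a fit of all 12 libraries and 1 to 168 without each library in turn. With the replicate number as a block it was 42 (37 up, 5 down), and the 4 genes stayed called. In this set the numbers do not pair the libraries (r −0.006, −0.029 and −0.023), and in deviations from group means no library correlates best with the one of its own number. Fcnb, Ndrg2 and Gm26712 did not pass without the filter (adjusted p = 0.131, 0.292 and 0.131). Ndrg2 did not pass with median-ratio scaling (0.0693) or quantile normalization (0.0601), Fcnb did not pass in the fit of all 12 libraries (0.0735), and Gm26712 did not pass without each of the compound PD libraries (0.0551 to 0.145).

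For the difference between compounds the count was 0. It was 3 without the filter, 3 with the split names as deposited and 0 to 15 without each library in turn. No gene was shared at an adjusted p under 0.10, with the block, or with a mean of at least 5 FPKM, and overlap was not counted under the other choices. Compound OB had 0 calls at an adjusted p under 0.10 and with a mean of at least 5 FPKM, so none could be shared there. With the block at most 0.00678 shared genes per direction were expected by chance. These settings therefore could not show whether the responses overlap.

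The number of called lists, 8 for compound OB and 12 for compound PD, was 0 for both with an estimated correlation and 0 for both with fry. For the difference 1 list of 12 remained with an estimated correlation. The p53 targets changed sign: without each library their median log2 ranged from −0.2803 to 0.1402 after compound OB (0.1402 without OB DMSO replicate 1) and from −0.134 to 0.0544 after compound PD (0.05 without PD DMSO replicate 1). The cause was not tested.

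Oxidative phosphorylation after compound OB also had a median of the other sign without OB DMSO replicate 1 (0.0042), OB DMSO replicate 3 (0.0121) or compound OB replicate 2 (0.0047), as did S phase genes after compound PD without PD DMSO replicate 2 (0.0038), while the direction of the set test stayed. By that direction, of the values with a library left out, 216 for called lists stayed the same, 46 were weaker and 2 turned over, and for named genes 236 stayed, 32 were stronger and 12 weaker. A gene that was not called and remained so counts as stayed. Of the named genes only the 4 called after compound PD could become weaker, and the 12 weaker values are those of Fcnb, Ndrg2 and Gm26712. Of the values under other choices, 59 for called lists stayed and 57 were weaker, and for named genes 350 stayed, 35 were stronger and 10 weaker. Both tallies for named genes also took in the number of called lists of each set. Of the 10 weaker values, some are such list numbers, with an estimated correlation or fry, and the rest are of Fcnb, Ndrg2 and Gm26712. DESeq2, RLE scaling and scaling to library size alone were planned for counts and were not run, because the values are FPKM.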

Other observations

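The following 6 genes of granulocytes are in no list and were picked after their values were seen, and none passed over all genes after compound PD without the replicate block. All 6 passed with the block, although the replicate numbers do not pair the libraries of this set. The stefins Stfa1 (1093 ± 185 in DMSO, 2708 ± 756 with compound PD, log2 1.28, adjusted p = 0.0973), Stfa2l1 (log2 1.12, 0.180) and Stfa3 (log2 1.01, 0.219) are protease inhibitors of granulocytes from near-identical genes, so that their single values are uncertain (SD, n = 3). The receptor Trem3 measured 17.0 ± 4.70 and 46.4 ± 3.09 (SD, n = 3; log2 1.43, adjusted p = 0.0851), the peptidoglycan-binding Pglyrp1 147 ± 37.7 and 333 ± 25.9 (SD, n = 3; log2 1.21, adjusted p = 0.0973), and the chitinase-like Chil3 374 ± 131 and 975 ± 309 (SD, n = 3; log2 1.39, adjusted p = 0.168).

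Single genes, also picked after their values were seen, stood out in compound PD replicate 1. The granule enzyme Mpo measured 933 there against 463 and 422 in the other treated libraries, the chymase Cma1 1389 against 703 and 701, and the carboxypeptidase Cpa3 1023 against 523 and 552. Megakaryocyte Pf4 measured 6017 there against 3232 and 3717.

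In the OB set replicate 1 stood apart in both groups for genes of unlike function. The peptide transporter Tap1 measured 7.39 in DMSO and 5.5 with compound OB, against 1.73, 1.94, 1.95 and 1.87 in the other 4 libraries. The red cell enzyme Bpgm measured 157 and 194, against 76.7 and 94.6 in the other DMSO libraries and 94.17 and 102.99 in the other treated ones.

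The nuclear long RNA Neat1 measured 383, 186 and 209 in OB DMSO replicates 1 to 3 and 347, 231 and 248 with compound OB. In PD DMSO replicate 1 it measured 755, against 310 and 309 in the other DMSO libraries of that set. Mitochondrially encoded genes held 1.83% to 2.34% of FPKM in the PD set.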
